A study of Mus musculus with 18 samples.

How the data were processed

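Hippocampus and cortex of male C57BL/6 mice that received UPM or vehicle through the nose were profiled with a 3' mRNA sequencing kit primed with oligo-dT, as single-end 75 bp reads, per the labels' protocols. RNA was pooled over the mice of a group, and the 18 files hold 1 library each. The deposited values are raw read counts per gene symbol, made by the authors with Bowtie2, bedtools and edgeR on the mouse build mm10 per the submitters' processing notes, without normalization. Versions, the role and order of those tools, the gene annotation, the strand setting and the treatment of reads with several hits are not stated. Each file was checked to hold whole numbers in 23282 lines with 23238 distinct symbols. Counts of repeated symbols were summed, and 27 symbols that a spreadsheet had turned into dates in 2 files were restored from the order of the other files. Total counts were 5.43 to 8.97 M per library, so 1 count equals 0.112 to 0.184 CPM, and a floor of 3 counts equals 0.335 to 0.552 CPM. Floors and the 95% Wilson intervals of shares cover counting error only. Akap5 and Lrrc17 had nearly equal counts in every library (ratio 0.99 to 1.011), as with reads counted for both, and they held 0.73% to 2.13% and 0.72% to 2.14% of the counts. No library was a copy of another (lowest chi-squared per degree of freedom between libraries 5.2).

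Groups followed the labels: control, short-term UPM (3, 5 and 7 days) and long-term UPM (3, 8, 12, 16 and 20 weeks) in each tissue. Because libraries of different times served as replicates, the p-values measure only the spread between these libraries and not that between mice. Exposure class and time go with the age of the mice, the dosing rhythm and the total dose, and the time of the control is not stated. Whether libraries of the same time pair across the tissues was checked by correlating, across genes, their deviations from the mean of tissue and library set. These gave r of -0.14 to 0.18 for the same time and -0.20 to 0.19 for different times. The comparisons over both tissues had tissue as a covariate, as chosen beforehand, and did not treat times as pairs. Correlations over all genes do not show that the libraries of a time are independent. Single genes stood apart in both tissues of a time, as Obp2a at 5 days (202 and 139 counts) and Shox2 at 8 weeks (331 and 156). If both tissues came from the same mice, these comparisons count them as separate samples. Among 3, 5 and 7 days and 3 weeks the same times gave 0.02 to 0.09 and different times -0.10 to 0.05, so a weak pairing is not excluded. With exposure time as a random block, fewer genes were called for short-term UPM against control and for the trend over weeks. In the comparison of tissues exposure time was a factor.

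Counts were scaled with TMM and filtered with filterByExpr, and tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05. Trends are slopes per 10 weeks. The tests were run on 18 libraries, on 9 of 1 tissue, on 10 of long-term exposure, or on subsets. Libraries were compared with the control of their tissue as log2 ratios of TMM-scaled CPM with a prior count of 2, and genes counted as 2-fold apart at an absolute log2 ratio of 1 with at least 50 counts in either library. CPM values in the text are TMM-scaled unless given per total counts. Of 39 gene lists fixed before the data were examined, the key genes served for naming only. Each of the 38 others, for cell types, neighbouring regions and responses to particles or stress, was tested with camera (limma 3.58.1) at a preset correlation of 0.01. The same test with an estimated correlation, and fry, were alternatives, adjusted over the lists of a comparison. The counts of list members that pass are given over all genes and adjusted over the list alone. The list called long non-coding RNAs in the text was fixed under the name short-lived and stress transcripts, as a measure of RNA quality and nuclear share, and GENCODE M21 gives its member Snhg11 as protein coding.

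Comparisons, lists, alternatives and the rule for naming genes were chosen before the data were examined. The rule names, per comparison, the 8 largest changes in each direction among genes past the threshold with a mean of at least 5 CPM (where fewer than 5 pass, those with the smallest p), the 3 list members with the smallest p, and a list of key genes. Per exposure time it names the 3 highest and 3 lowest by the mean log2 ratio over both tissues. Of 629 named genes 618 had a position in GENCODE M21 on GRCm38, the assembly of mm10. The comparisons between and within the 2 library sets, and the terms for the set, were chosen after the data were seen.

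Alternatives were DESeq2 1.42.0, limma-voom, RLE size factors, total counts alone, no filter, a mean of 50 counts in every group, a fold above 1.5, and fits without marker genes of neighbouring regions and blood and the 20 genes with the most counts. Others left out each library or each time, summed both tissues, took exposure time as a random block, or counted 3 weeks as short-term. The groups of libraries were also split in other ways, at most 100 per comparison, with a fixed seed. The models were tested on simulated negative binomial counts with the dispersion of each gene, in which 200 genes were changed. Of the genes changed 2-fold they recovered 71.6% for the tissue difference, 40.9% and 53% for long-term against short-term UPM in hippocampus and cortex, and 13.6% for the difference between them. For UPM against control they recovered 50.7% over all exposed libraries, 49.2% for short-term, 41.8% for long-term and 62.1% within the control and late set. For the trends it was 85.1% over 3 to 20 weeks and 80.3% over 8 to 20 weeks, and for the library sets 91%. At most 0.074% of unchanged genes were called. The simulated counts were independent around a mean per tissue, without library sets or carried-over tissue. This share therefore does not cover calls that such structure gives in the real libraries. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served for the remaining steps.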

Results

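Gene expression was measured in the hippocampus and the cortex of male C57BL/6 mice given urban particulate matter (UPM), a collected city dust that carries metals and combustion products, or its vehicle, phosphate-buffered saline, through the nose. The mice were 7 weeks old at the start. UPM was given daily for 3, 5 or 7 days, named short-term by the labels. Other mice received it 2 times per week for 3, 8, 12, 16 or 20 weeks, named long-term. RNA of the mice of a group was pooled, so each tissue had 3 short-term libraries, 5 long-term libraries and 1 control library, 18 libraries in all. The libraries came from the 3' ends of polyadenylated RNA, and the values are read counts per gene symbol. In hippocampus the total count was 7.96 M counts in the control, 5.84, 5.43 and 7.37 M at 3, 5 and 7 days, and 7.08, 8.08, 7.51, 7.56 and 7.53 M at 3, 8, 12, 16 and 20 weeks. In cortex it was 7.49 M in the control, 8.97, 8.20 and 8.23 M at 3, 5 and 7 days, and 8.59, 7.34, 8.31, 8.65 and 7.31 M at 3, 8, 12, 16 and 20 weeks. No exposure time had a replicate. Libraries of different times stood in for replicates of their class, so the spread of a class holds the differences between its times.

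The libraries fell into 2 sets that did not follow the exposure classes. Columns of the 3-, 5- and 7-day and 3-week libraries were named in one way in the file headers, and those of the control and the 8-, 12-, 16- and 20-week libraries in another. These are called the early set (8 libraries) and the control and late set (10 libraries). Rn45s, the gene of the ribosomal RNA precursor, took 14.83% to 18.61% of the counts in the early set and 7.75% to 12.88% in the control and late set, with 95% Wilson intervals within 0.03 percentage points of each share. Ribosomal protein genes took 1.42% to 2.05% and 1.16% to 1.38% of the counts. At an equal total of 5.43 M counts, Rn45s included, 14643 to 15922 genes were detected in the early set and 16257 to 16977 in the other. The counts left for other genes were thus fewer in the early set. The first principal component of log2 CPM, with 25.8% of the variance, ran from -65.7 to -20.8 in the early set and from 22.6 to 43.1 in the control and late set. The second, with 16.9%, ran from 1.3 to 40.1 in hippocampus and from -48.5 to -18.1 in cortex.

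**Figure D1:**
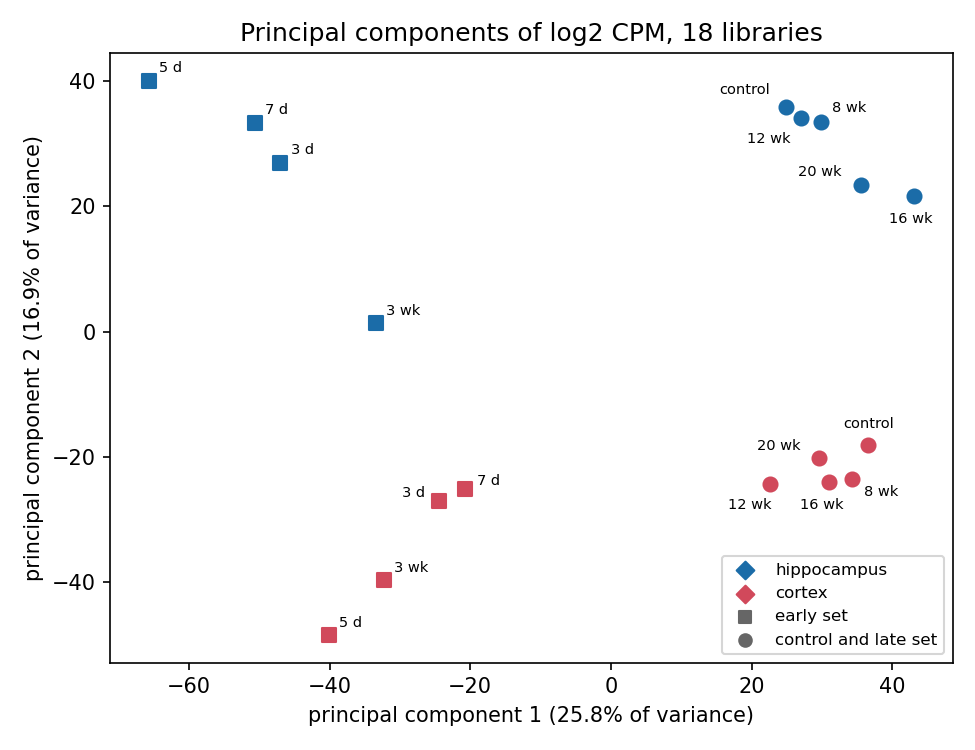
Principal components 1 and 2 of log2 CPM, in arbitrary units, with 1 point per library; colour gives the tissue and shape the library set. The early set lies at -65.7 to -20.8 on component 1 and the control and late set at 22.6 to 43.1, while component 2 separates the tissues.

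The difference between the tissues gave the background against which exposure was read. Genes of hippocampal neurons stood higher in hippocampus, among them Dsp, a desmosome gene of dentate granule cells (chromosome 13, 38151294 to 38198577; log2 fold change 6.05 ± 0.41 SE, 9 libraries per tissue), Fibcd1, a marker of the CA1 field (3.57 ± 0.25), and C1ql2, a synaptic protein of mossy fibres (4.16 ± 0.30). The cortical neuron genes lower in hippocampus included Foxp2, a transcription factor of deep cortical layers (chromosome 6, 14901349 to 15441977; -2.68 ± 0.23), Mef2c (-1.91 ± 0.17) and the layer IV marker Rorb (-1.21 ± 0.10). Adora2a, the adenosine receptor gene of projection neurons in the neighbouring striatum (chromosome 10, 75316877 to 75334784), was lower as well, at -4.12 ± 0.45. Gfap, the astrocyte intermediate filament gene (1.57 ± 0.14), and Serpina3n, a gene of reactive astrocytes (1.87 ± 0.21), were higher in hippocampus.

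With exposure time as a factor, edgeR called 2507 of 14865 genes between the tissues, 1130 higher and 1377 lower in hippocampus (smallest adjusted p = 1.52e-09). With total counts alone the balance turned over, with 1446 higher and 980 lower. Of 21 hippocampal neuron genes tested, 16 were higher and 1 lower and 4 did not pass (adjusted over the list alone, 17 and 1). The list as a whole was higher (camera adjusted p = 1.98e-31; adjusted p = 0.00087 with an estimated correlation). Of 22 cortical neuron genes, 15 were lower and 2 higher (adjusted over the list alone, the same counts). The list had adjusted p = 2.13e-16, and adjusted p = 0.0629 with an estimated correlation. All but 1 of the 16 striatal genes were lower, 15 over all genes and 16 adjusted over the list alone (adjusted p = 1.8e-14; adjusted p = 0.226 with an estimated correlation). Of 15 astrocyte genes 9 were higher and none lower, and of 21 reactive astrocyte genes 7 were higher (adjusted over the list alone, 9 and 7). Their list tests gave adjusted p = 0.000692 and 8.73e-05, and adjusted p = 0.299 and 0.226 with an estimated correlation. Among 22 immediate early genes, which follow neuronal activity, 10 were lower and 3 higher (adjusted over the list alone, 13 and 3). Egr1 stood at -1.06 ± 0.14, Jun at 0.80 ± 0.10 and Nr4a3 at 1.37 ± 0.18. The list had adjusted p = 0.0019, and adjusted p = 0.445 with an estimated correlation. Interneuron and neuropeptide genes were lower in 8 of 21 and higher in 2 (adjusted over the list alone, 10 and 3). Crh, the gene of the stress peptide corticotropin-releasing hormone, stood at -1.75 ± 0.18 and Npy at -0.91 ± 0.11. This list had adjusted p = 0.000536, and adjusted p = 0.119 with an estimated correlation. Of 20 key genes measured, 6 were higher in hippocampus (Gfap, Apoe, Bdnf, Mt1, Mt2 and C4b) and 2 lower (Arc and Dcx). The other 12 did not pass, from Npas4 at -0.83 to Ttr at 2.48. The count was 349 when a fold above 1.5 was required and 656 within the early set, against 2912 within the control and late set.

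Marker genes of neighbouring structures varied between single libraries. Ttr, the transthyretin gene that choroid plexus expresses at very high level (chromosome 18, 20665280 to 20674321), ranged from 20.2 to 6590 CPM among hippocampal libraries and from 8.45 to 4060 CPM among cortical ones. The mean level of the striatum list ranged from -1.38 at 7 days to 1.37 at 5 days in cortex, and that of the thalamus and habenula list reached 1.28 in hippocampus and 0.86 in cortex at 8 weeks. In hippocampus the cortical neuron list ran from -0.77 at 7 days to 0.66 at 3 weeks, and the hypothalamus list reached 2.25 at 8 weeks. Mef2c stood at 1300, 1620 and 1380 CPM of total counts in hippocampus at 3, 16 and 20 weeks. It stood at 507 in the control and 437 to 824 in the others. The 16-week hippocampus lay nearer to the cortical control (chi-squared per degree of freedom 14.49) than to the hippocampal one (18.11). It lay nearer still to the hippocampus at 12 weeks (12.17) and 20 weeks (14.02), but not at 8 weeks (14.71). On component 2 it lay among the hippocampal libraries, at 21.7. Genes with many counts weigh most in this measure. Ttr had 37886 counts there, 266 in the hippocampal control and 8632 in the cortical control. Cortical carry-over was not tested.

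**Figure D2:**
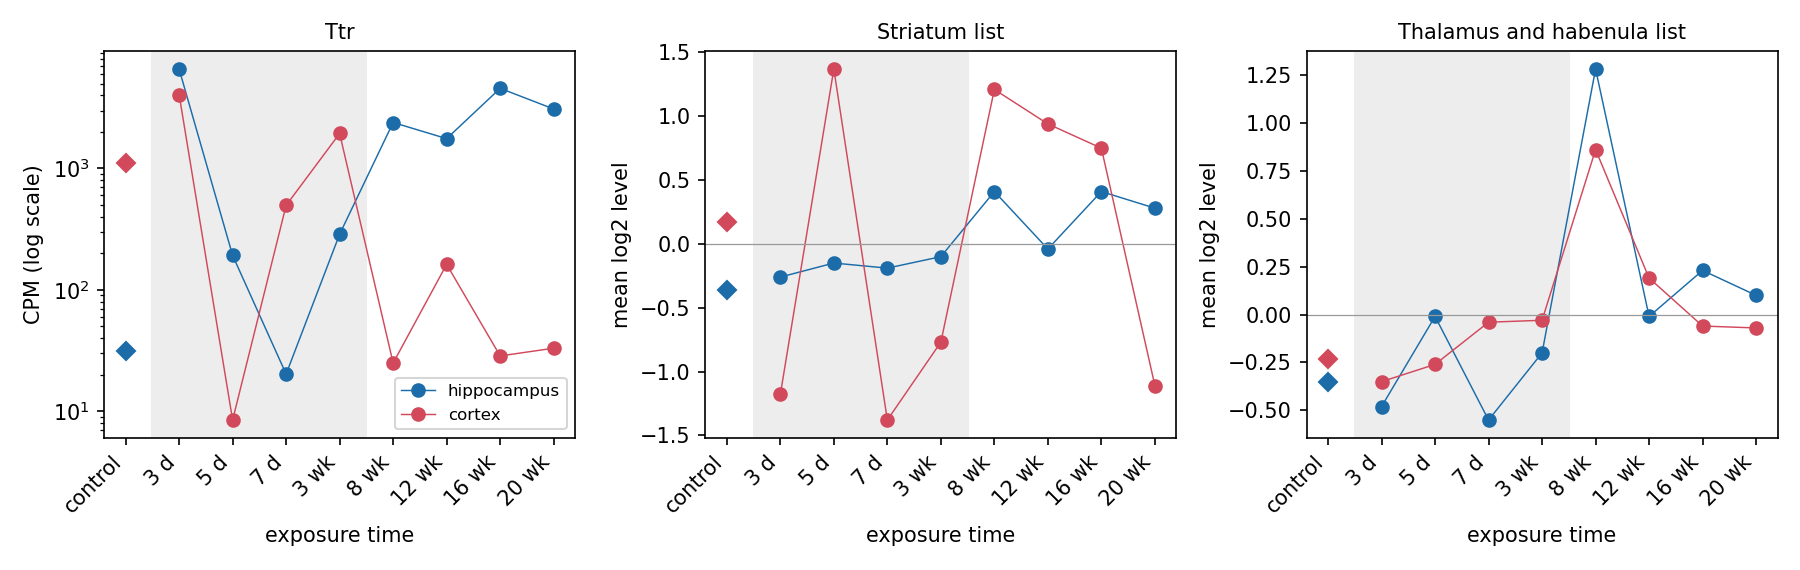
Ttr in CPM on a log scale (left), and the mean log2 level, centred per gene within each tissue, of the striatum list (middle) and of the thalamus and habenula list (right), for each library by exposure time; diamonds are controls and grey shading marks the early set. Ttr runs from 20.2 to 6590 CPM in hippocampus, and the thalamus list stands at 1.28 and 0.86 at 8 weeks.

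The comparison of long-term with short-term exposure in hippocampus asks whether the length of exposure alters expression. The long non-coding RNAs Meg3, which is imprinted (chromosome 12, 109541001 to 109571726; log2 fold change 2.70 ± 0.46 SE, 5 against 3 libraries), Miat (2.61 ± 0.47) and Snhg11 (2.68 ± 0.42) were higher in the long-term libraries. Cep70, which encodes a centrosomal protein, was higher by 2.18 ± 0.24 (adjusted p = 0.0127), and Vegfa, the angiogenic growth factor, by 1.10 ± 0.19 (adjusted p = 0.049). Pfn1, which encodes the actin-binding protein profilin (-1.30 ± 0.22), Ccng2, a cyclin (-1.23 ± 0.20), and Banf1, a chromatin protein (-0.86 ± 0.15), were lower.

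edgeR called 35 of 15229 genes, 29 higher and 6 lower in long-term hippocampus. Of 8 long non-coding RNAs tested, 3 were higher (adjusted over the list alone, 7), with a list median of 2.60 (camera adjusted p = 1.83e-09; adjusted p = 0.49 with an estimated correlation). None of the 83 oxidative phosphorylation genes passed over all genes, with a median of -0.37, or -0.21 with total counts alone (adjusted over the list alone, 15 lower; list adjusted p = 7.14e-18, and adjusted p = 0.696 with an estimated correlation). Cox5b stood at -0.56 ± 0.12 with adjusted p = 0.0539. None of the 81 ribosomal protein genes passed either way, with a median of -0.38, or -0.22 with total counts alone (list adjusted p = 2.65e-16; adjusted p = 0.696 with an estimated correlation). Of 18 ER stress genes none passed over all genes (adjusted over the list alone, 8 lower), with Pdia4 at -1.15 ± 0.22. Their median was -0.30, or -0.12 with total counts alone, and their mean 0.01. The list test pointed down (list adjusted p = 0.000609; adjusted p = 0.49 with an estimated correlation). No key gene passed among 19 measured, the extremes being Nqo1 at -0.99 ± 0.59 and Npas4 at 2.56 ± 0.73. The short-term libraries all belonged to the early set and 4 of the 5 long-term libraries to the control and late set. A term for the set can then be estimated from the 3-week library alone, and does not tell the set from time. Within the early set, 3 weeks against 3 to 7 days, edgeR called 0 of 13932 genes (291 at an unadjusted p under 0.05; no other tool was run on these 4 libraries). With the set as a term it called 0 of the genes tested. The count was 1116 with DESeq2 (732 higher and 384 lower), 0 with limma-voom, 1 with RLE size factors and 558 with total counts alone (529 and 29). It was 0 when the 3-, 5- or 7-day or the 8-week library was left out, 2195 without 3 weeks (1117 higher and 1078 lower), 2 without 12 weeks, and 1 without 16 or without 20 weeks.

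In cortex the same comparison gave no gene past the threshold. The smallest adjusted p was that of Ddn, the dendrin gene of postsynaptic sites (chromosome 15, 98803777 to 98809490), at -0.97 ± 0.13 (5 against 3 libraries, adjusted p = 0.0708), followed by Ccl27b at 1.17 and Limd2 at -0.82. Of 8 long non-coding RNAs none passed over all genes (adjusted over the list alone, 6 higher), with a median of 1.70 (list adjusted p = 9.86e-05; adjusted p = 0.435 with an estimated correlation). Red blood cell genes had a median of -0.86 (adjusted over the list alone, 8 of 8 lower; list adjusted p = 1.05e-05, and adjusted p = 0.435 with an estimated correlation). Homeostatic microglia genes had a median of -0.42 over 21 genes (adjusted over the list alone, 5 lower; list adjusted p = 1.25e-05, and adjusted p = 0.435 with an estimated correlation). Choroid plexus genes had a median of -1.62 over 17 genes, with 0 passing (list adjusted p = 0.00827; adjusted p = 0.697 with an estimated correlation), Ttr standing at -1.80. Of 20 key genes none passed, from Ttr at -1.80 to Cldn5 at 0.72. edgeR called 0 of 14936 genes, with 3081 at an unadjusted p under 0.05, where DESeq2 called 667 and limma-voom 9. The count rose to 3041 without the 3-week library, the only long-term library of the early set. Within that set edgeR called 0 of 14285 genes, with 491 at an unadjusted p under 0.05.

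In edgeR no gene passed the threshold for a difference between the tissues in its long-term against short-term change. Cdh13, which encodes a cadherin (1.38), and Ctsh, a lysosomal protease gene (1.77), had differences of hippocampus minus cortex that did not pass. As lists, choroid plexus genes (median difference 1.88, 17 of 17 positive, camera adjusted p = 0.000109), mural cell and fibroblast genes (1.48, 16 of 17, adjusted p = 8.7e-06) and homeostatic microglia genes (0.39, 19 of 21, adjusted p = 0.00113) lay above 0. All 3 had adjusted p = 0.872 with an estimated correlation. edgeR called 0 of 15598 genes (1252 at an unadjusted p under 0.05), limma-voom 0 and DESeq2 25. None of 20 key genes passed, from Cldn5 at -0.67 to Npas4 at 2.11.

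UPM exposure of any length was compared with the control over both tissues. The activated microglia list, genes that microglia raise on activation and antigen presentation, stood above the control. Of its genes 18 of 18 had a positive log2 fold change, with a median of 0.42 (16 exposed against 2 control libraries, camera adjusted p = 9.01e-06; adjusted p = 0.0115 with an estimated correlation; fry adjusted p = 0.0299). No single gene passed, over all genes or adjusted over the list alone. Spp1, the osteopontin gene (chromosome 5, 104435118 to 104441050), stood at 2.20, Cd52 at 1.73, and the class II antigen gene H2-Eb1 at 1.30. Blood leukocytes express Cd52 and class II genes too, and 4 of 4 blood leukocyte genes were positive with a median of 2.03 and none passing (list adjusted p = 0.246; adjusted p = 0.651 with an estimated correlation). Red blood cell genes were positive in 8 of 8 with a median of 0.75 and none passing (list adjusted p = 0.000859; adjusted p = 0.651 with an estimated correlation). The long non-coding RNA list, fixed as a measure of RNA quality, had a median of -0.88 in the same comparison. Spp1 lay at 0.469 CPM in the hippocampal control and at 1.19 to 5.49 CPM in exposed hippocampus, and at 0.891 CPM in the cortical control and 0.556 to 5.94 CPM in exposed cortex. Of the 38 lists, activated microglia and NRF2 and antioxidant genes had the lowest of 9 mean levels in the control of both tissues, where 0.94 lists would be so placed at one end by chance.

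**Figure D3:**
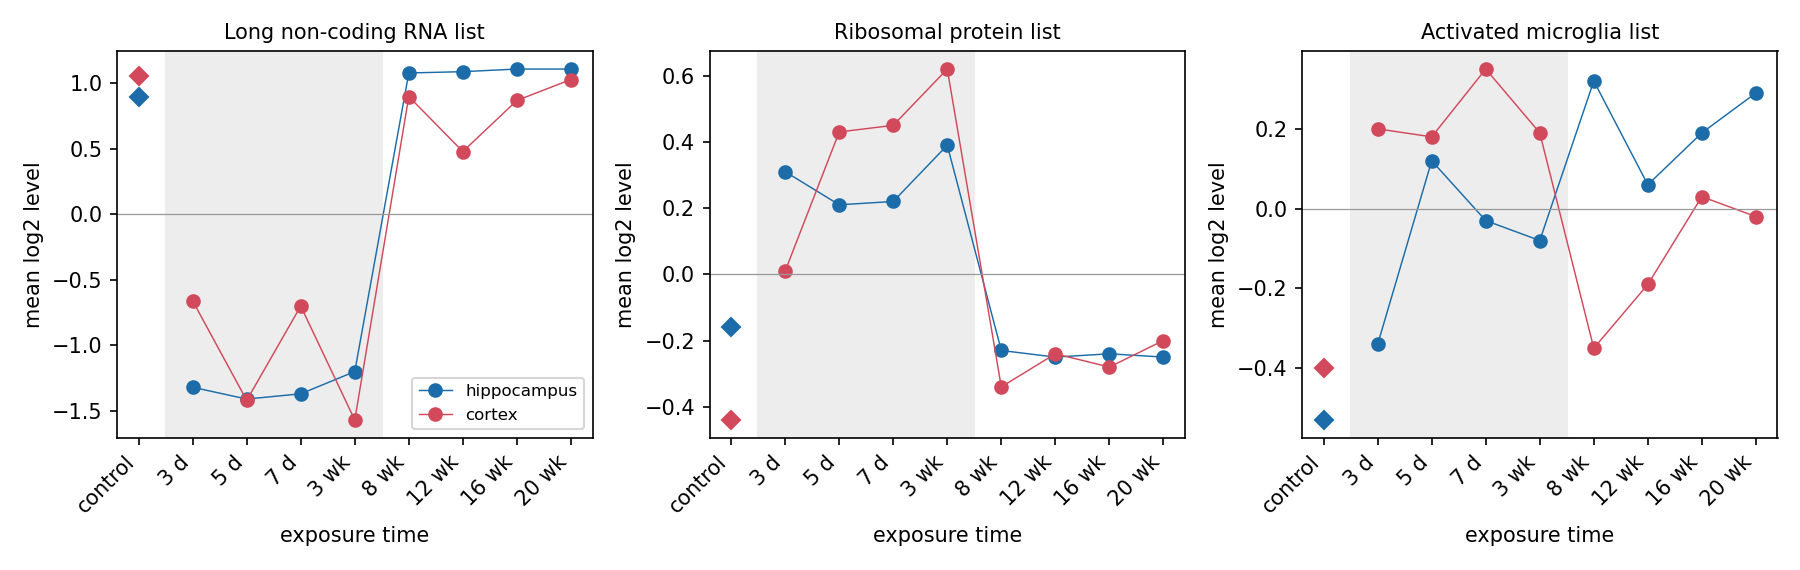
Mean log2 level, centred per gene within each tissue, of the long non-coding RNA list (left), the ribosomal protein list (middle) and the activated microglia list (right) in each library by exposure time; diamonds are controls and grey shading marks the early set. The activated microglia list is lowest in the control of both tissues, at -0.53 in hippocampus and -0.40 in cortex, and the long non-coding RNA list follows the shading.

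NRF2 and antioxidant genes had a median of 0.18, or 0.08 with total counts alone, over 24 genes with 0 passing (list adjusted p = 0.000995; adjusted p = 0.651 with an estimated correlation), Nqo1, a quinone reductase gene, standing at 1.03 and Hmox1, heme oxygenase, at 0.04. Immediate early genes had a median of -0.22 with 3 of 22 positive (list adjusted p = 0.00551; adjusted p = 0.651 with an estimated correlation). The ribosomal protein list (median 0.40, adjusted p = 1.58e-19) and the homeostatic microglia list (0.34, adjusted p = 9.01e-06) also had adjusted p = 0.651 with an estimated correlation. None of 20 key genes passed, from Dcx at -0.31 to Nqo1 at 1.03, with Gfap at 0.21, Aif1 at 0.67, Il1b at 0.48 and Apoe at 0.43. edgeR called 0 of 14865 genes, with 272 at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. Both controls were of the control and late set. Within that set the comparison of 8 exposed with 2 control libraries also gave 0 of 14465 genes in edgeR, DESeq2 and limma-voom, with 676 at an unadjusted p under 0.05. There the activated microglia list had 16 of 18 genes positive and a median of 0.46 (adjusted p = 2.61e-05; adjusted p = 0.0615 with an estimated correlation), and fry called 0 of 38 lists. In that set 4 lists had the control lowest or highest in both tissues where 3.04 were expected. Beside it, thalamus and habenula genes had a median of 0.63 and striatal genes of 0.46 (adjusted p = 7.01e-05 and 0.000687; adjusted p = 0.621 and 0.759 with an estimated correlation). Without the hippocampal control the within-set count was 1 and without the cortical control 4.

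Short-term UPM against the control, over both tissues, gave lower levels of the long non-coding RNAs Miat (-2.85 ± 0.51), Meg3 (-2.77 ± 0.52) and Snhg11 (-2.62 ± 0.47; 6 against 2 libraries). Collagen genes Col5a1 (-2.60 ± 0.62), Col6a1 (-2.16 ± 0.54) and Col4a2 (-1.37 ± 0.35) fell as well. With the set as a term, which rests on 3 weeks against the later weeks, Col6a1 and Col4a2 turned to 0.12 and 0.01. Sst, the somatostatin gene of interneurons, also fell (-0.84 ± 0.21). Astrocyte genes S100b (0.96 ± 0.22) and Glul, glutamine synthetase (0.72 ± 0.17), rose, together with Pdia4, an ER chaperone gene (1.58 ± 0.37), and Sdc4, a cell surface proteoglycan gene (1.23 ± 0.24).

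edgeR called 288 of 14865 genes, 47 higher and 241 lower after short-term UPM (smallest adjusted p = 0.0166), and with total counts alone 55 higher and 748 lower. Of 8 long non-coding RNAs 5 were lower (adjusted over the list alone, 6; list adjusted p = 2e-09, and adjusted p = 0.15 with an estimated correlation). Of 84 oxidative phosphorylation genes 2 were higher, Cox5b (0.57 ± 0.13) and Atp5g2 (0.65 ± 0.17), and of 81 ribosomal protein genes none over all genes (adjusted over the list alone, 28 higher, and 47 higher with 1 lower). Their list tests gave adjusted p = 1.02e-16 and 7.13e-21, and adjusted p = 0.452 and 0.468 with an estimated correlation. Of 19 collagen and matrix genes 3 were lower (adjusted over the list alone, 5; list adjusted p = 0.0456, and adjusted p = 0.758 with an estimated correlation). Of 15 astrocyte genes 2 were higher (adjusted over the list alone, 3; list adjusted p = 0.0063, and adjusted p = 0.398 with an estimated correlation). Activated microglia genes had a median of 0.50, or 0.31 with total counts alone, with 14 of 18 positive and none passing (adjusted p = 0.00243; adjusted p = 0.109 with an estimated correlation). Blood leukocyte genes had a median of 2.48, 4 of 4 positive and none passing (adjusted p = 0.523; adjusted p = 0.82 with an estimated correlation). Red blood cell genes had one of 1.17, with 0 passing over all genes (adjusted over the list alone, 7 of 8 higher; adjusted p = 2.59e-05, and adjusted p = 0.36 with an estimated correlation). None of 20 key genes passed, from Npas4 at -1.13 to Nqo1 at 1.49, with Apoe at 0.67 (adjusted p = 0.0512). All short-term libraries were of the early set and both controls of the other, and with the set as a term edgeR called 0 genes. That term rests on 3 weeks against 8 to 20 weeks and also takes up changes with time. The 0 therefore does not decide between the set and the exposure. The count was 0 with exposure time as a random block, when a fold above 1.5 was required, and without the 5-day libraries, the cortical 5-day library alone, or either control. It was 167 without the 7-day, 2011 without the 3-week, 19 without the 8-week, 18 without the 12-week, 72 without the 16-week and 171 without the 20-week libraries of both tissues. Leaving out 1 hippocampal library gave 74 without 5 days, 156 without 7 days, 825 without 3 weeks and 186 without 12 weeks. For cortical libraries it was 1169 without 3 weeks, 167 without 12 weeks and 179 without 16 weeks.

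Long-term UPM against the control gave no gene past the threshold. The activated microglia list again stood above the same controls, with 16 of 18 genes positive and a median of 0.53 (10 against 2 libraries, camera adjusted p = 4.3e-06; adjusted p = 0.00507 with an estimated correlation; fry adjusted p = 0.0452). The 3-week libraries among these were of the early set. Without them, within the control and late set, the list did not pass with an estimated correlation, and fry called 0 of 38 lists. Spp1 stood at 2.17, Cd52 at 1.51 and H2-Ab1, a class II antigen gene, at 1.38. Blood leukocyte genes had a median of 1.39, 4 of 4 positive (adjusted p = 0.13; adjusted p = 0.609 with an estimated correlation), and red blood cell genes one of 0.43, 6 of 8 positive (adjusted p = 0.0357; adjusted p = 0.613 with an estimated correlation). Foxo6, a forkhead transcription factor gene, at -0.78, Gatm, which encodes an enzyme of creatine synthesis, at 0.85 and S100a6, a calcium-binding protein gene, at 0.73 were among the smallest p-values, with adjusted p = 1 for each. Myelin genes had a median of 0.27, 19 of 20 positive (adjusted p = 0.00343; adjusted p = 0.613 with an estimated correlation), but single libraries went both ways. Their median log2 ratios to the control at 3, 8, 12, 16 and 20 weeks were 0.37, 1.13, 0.66, 0.53 and -0.54 in hippocampus and 0.05, 0.45, -0.12, -0.10 and -0.53 in cortex. Thalamus and habenula genes had a median of 0.70 (adjusted p = 0.000591; adjusted p = 0.453 with an estimated correlation). The long non-coding RNA list, fixed as a measure of RNA quality, had one of -0.41. None of 20 key genes passed, from Arc at -0.14 to Nqo1 at 0.68. edgeR called 0 of 14865 genes, with 185 at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0.

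The trend over 3 to 20 weeks of UPM asks whether expression changes with accumulating exposure. The small nucleolar RNA genes Snora81 (chromosome 16, 23110756 to 23110933; -6.84 ± 0.88 per 10 weeks on the log2 scale) and Snord49b (-4.08 ± 0.47; 10 libraries) fell, though the slope of Snora81 was 0.42 with the set as a term. Nts, the neurotensin gene, fell (-1.37 ± 0.18), as did Pvalb, the parvalbumin gene of interneurons (-0.85 ± 0.15), and Mt2, a metallothionein gene that metals induce (-0.55 ± 0.08). The myelin genes Mog (-1.04 ± 0.22), Opalin (-0.94 ± 0.18) and Mbp (-0.67 ± 0.15) fell. Col6a1 (1.41 ± 0.20), Plk5 (1.35 ± 0.19) and Vegfa (0.51 ± 0.10) rose.

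edgeR called 487 of 14087 genes, 142 rising and 345 falling (smallest adjusted p = 0.013). With total counts alone it called 183, and the balance turned over, with 120 rising and 63 falling. Of 83 oxidative phosphorylation genes 25 fell, for example Ndufa7 at -0.61 ± 0.11 and Uqcrh at -0.67 ± 0.12, and of 81 ribosomal protein genes 12 fell, for example Rps27l at -0.90 ± 0.14 and Rps14 at -0.77 ± 0.16 (adjusted over the list alone, 56 falling, and 66 falling with 1 rising). With total counts alone 5 and 1 of these fell over all genes, and 0 of the myelin genes, with list medians of -0.21, -0.28 and -0.41. The long non-coding RNA list, fixed as a measure of RNA quality, moved the other way, with a median slope of 1.11 and 0 of 8 passing over all genes (adjusted over the list alone, 6 rising; list adjusted p = 0.000109, and adjusted p = 0.808 with an estimated correlation). Of 20 myelin genes 7 fell (adjusted over the list alone, 11), and of 23 NRF2 and antioxidant genes 3 fell, Prdx1 (-0.64 ± 0.11), Gstm5 (-0.74 ± 0.14) and Gpx4 (-0.43 ± 0.11; adjusted over the list alone, 5). The list tests gave adjusted p = 1.54e-22 for oxidative phosphorylation, 1.95e-24 for ribosomal proteins, 7.84e-08 for myelin and 0.0259 for NRF2 and antioxidant genes, each with adjusted p = 0.808 with an estimated correlation. The NRF2 median was -0.09 and turned to 0.02 with total counts alone. Of 18 key genes Mbp and Mt2 fell, and the other 16 did not pass, from Ttr at -1.76 to Npas4 at 0.25. The 3-week libraries were the only ones of the early set here. Without them 40 genes were called, 10 of them among the 487, and with the set as a term 31. The count was 20 with exposure time as a random block, 0 with both tissues summed and 2 when a fold above 1.5 was required. It was 2697 without 8 weeks, 0 without 12 or without 16 weeks, and 6 without 20 weeks in both tissues. Leaving out 1 hippocampal library gave 0 without 3 weeks, 1408 without 8 weeks, 19 without 12 weeks, 42 without 16 weeks and 87 without 20 weeks. Leaving out 1 cortical library gave 0, 1720, 17, 21 and 8 in the same order.

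Within the control and late set, over 8 to 20 weeks, the falling genes included 11 myelin genes among 38, in a comparison chosen after the library sets were seen. Mobp, a structural protein of central myelin (chromosome 9, 120149707 to 120181484), fell by 1.56 ± 0.17 per 10 weeks on the log2 scale (8 libraries, adjusted p = 0.00935). Mog, the oligodendrocyte glycoprotein on the myelin surface (-1.57 ± 0.21), Mag, which joins myelin to the axon (-1.23 ± 0.15), Cldn11, a myelin tight junction gene (-1.33 ± 0.18), Mal (-1.31 ± 0.17), Tspan2 (-1.23 ± 0.14) and Mbp, myelin basic protein (-0.98 ± 0.17), fell as well. Mog went from 75.6 CPM at 8 weeks to 39.6, 38.7 and 13.7 CPM at 12, 16 and 20 weeks in hippocampus, and from 44.3 to 26.6, 27.4 and 12.0 CPM in cortex, against 28.7 and 38.4 CPM in the controls. Olig1, a transcription factor of the lineage, fell by 0.56 ± 0.09, Sgk1, a glucocorticoid-induced kinase gene, by 1.39 ± 0.25 and Mt2 by 0.64 ± 0.10, while Pter (0.62 ± 0.11) and Nr2f1 (0.53 ± 0.09) rose.

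**Figure D4:**
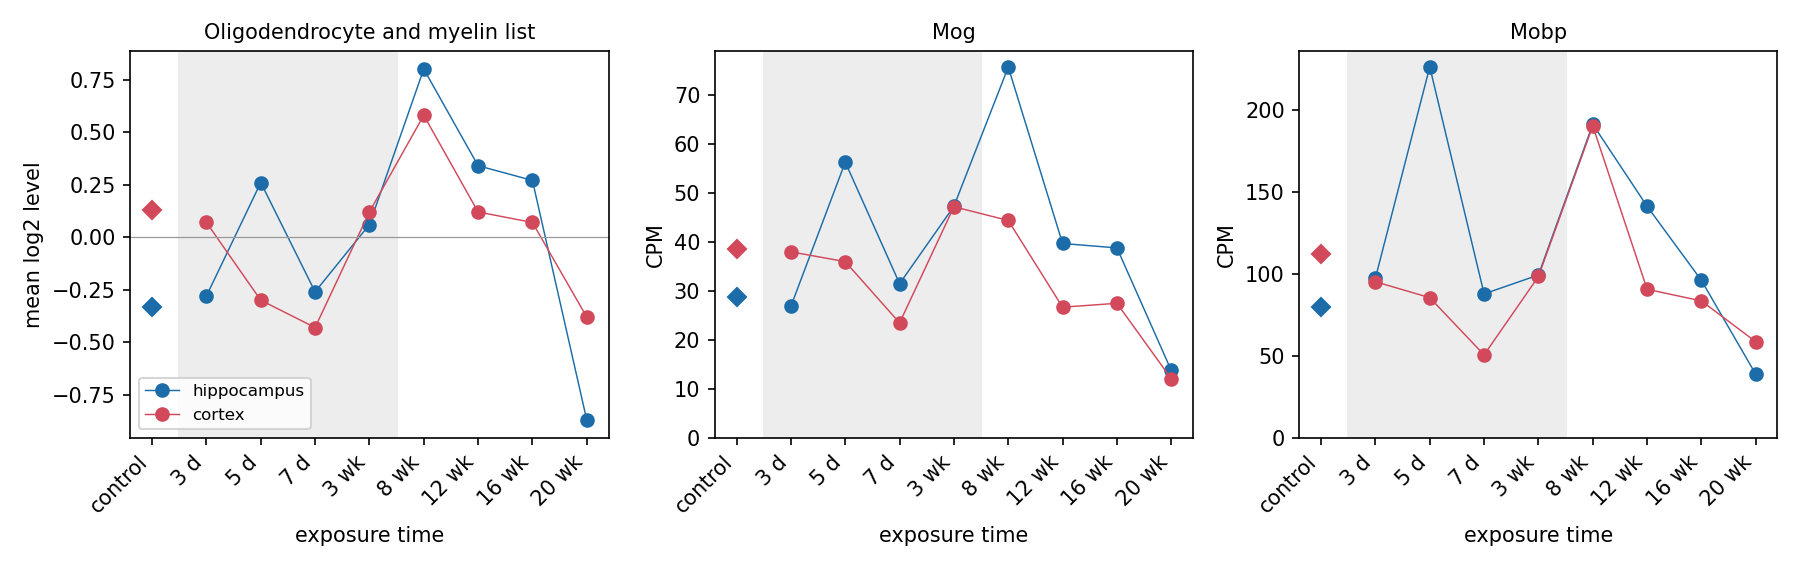
Mean log2 level of the oligodendrocyte and myelin list, centred per gene within each tissue (left), and CPM of Mog (middle) and Mobp (right), in each library by exposure time; diamonds are controls and grey shading marks the early set. From 8 to 20 weeks the list goes from 0.80 to -0.87 in hippocampus and from 0.58 to -0.38 in cortex, with the controls at -0.33 and 0.13.

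edgeR called 40 of 13968 genes in this trend, 2 rising and 38 falling. Of 20 myelin genes 11 fell and 9 did not pass (adjusted over the list alone, 17 fell), with all 20 slopes negative and a median of -1.05 (camera adjusted p = 1.89e-68; adjusted p = 0.0501 with an estimated correlation; fry adjusted p = 0.0487). Of 12 oligodendrocyte precursor genes 1 fell (adjusted over the list alone, 6; list adjusted p = 1.04e-09, and adjusted p = 0.0388 with an estimated correlation). Of 17 glucocorticoid response genes 2 fell, Sgk1 and Mt2 (adjusted over the list alone, 6; list adjusted p = 7.75e-10, and adjusted p = 0.277 with an estimated correlation). Markers of neighbouring regions moved in the same libraries. The thalamus and habenula list had a median slope of -0.71 (adjusted over the list alone, 9 of 15 fell; list adjusted p = 7.75e-10, and adjusted p = 0.277 with an estimated correlation). The striatum list had a median slope of -0.66 (adjusted p = 2.2e-08; adjusted p = 0.464 with an estimated correlation). Of 18 key genes Mbp and Mt2 fell, and Mt1 (-0.39 ± 0.07) had adjusted p = 0.0556. The count was 0 without 8 weeks, 14 without 12, 89 without 16 and 2 without 20 weeks in both tissues. It was 10 with both tissues summed, 0 when a fold above 1.5 was required, and 18 with the striatum level as a covariate. Leaving out 1 hippocampal library gave 0 without 8, 71 without 16 and 13 without 20 weeks, and 1 cortical library 0 without 8, 17 without 12 and 14 without 20 weeks.

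The difference between the library sets, in a comparison chosen after the sets were seen, gave the largest number of genes. The long non-coding RNAs Miat (2.70 ± 0.14, 10 against 8 libraries), Meg3 (2.62 ± 0.18) and Snhg11 (2.48 ± 0.15) were higher in the control and late set. The small nucleolar RNA genes Snora81 (-7.52 ± 0.26) and Snord49b (-5.10 ± 0.24) and the dendritic RNA gene Bc1 (-3.19 ± 0.15) were lower. Timm22, a mitochondrial import gene (chromosome 11, 76406952 to 76416292; -3.15 ± 0.11), Ccdc36 (-3.35 ± 0.11) and Pex13, a peroxisome gene (-3.29 ± 0.13), were lower too. The basement membrane collagen genes Col4a1 (1.11 ± 0.13) and Col4a2 (1.28 ± 0.15) were higher. The liver urinary protein genes Mup2 (3.41 ± 0.84) and Mup7 (3.76 ± 0.88) also passed, but a large part came from 1 library, the 16-week hippocampus (107 and 72.5 CPM), without which they stood at 2.29 and 2.56.

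edgeR called 5486 of 13864 genes, 2658 higher and 2828 lower in the control and late set, and 4376 among the long-term libraries alone, where 3 weeks stood against 8 to 20 weeks. Of 81 ribosomal protein genes 78 were lower (median -0.66, adjusted over the list alone, 78; list adjusted p = 2.41e-41, and adjusted p = 0.173 with an estimated correlation). Of 83 oxidative phosphorylation genes 66 were lower and 1 higher (adjusted over the list alone, 66 and 2; adjusted p = 2.21e-32, and adjusted p = 0.0976 with an estimated correlation), for example Ndufa4 at -1.03 ± 0.07. Of 8 long non-coding RNAs 7 were higher over all genes and adjusted over the list alone (adjusted p = 1.38e-18; adjusted p = 0.00279 with an estimated correlation). Homeostatic microglia genes were lower in 10 of 21 and higher in 1 (adjusted over the list alone, 11 and 1; adjusted p = 0.00886, and adjusted p = 0.559 with an estimated correlation), for example C1qc, a complement gene, at -0.79 ± 0.13. NRF2 and antioxidant genes were lower in 8 of 23 over all genes and adjusted over the list alone (adjusted p = 0.00886; adjusted p = 0.173 with an estimated correlation), with a median of -0.15 that turned to 0.04 with total counts alone. Red blood cell genes were lower in 7 of 8 by either adjustment (adjusted p = 0.00274; adjusted p = 0.559 with an estimated correlation). Of 18 key genes Apoe (-0.52 ± 0.07), Aif1 (-0.61 ± 0.15), Mt1, Mt2 and Bdnf were lower and Dcx higher. The other 12 did not pass, from Ttr at -1.19 to Npas4 at 0.63. With total counts alone the median log2 fold change of all genes moved from 0 to 0.19 and the counts to 4577 higher and 1346 lower. When a fold above 1.5 was required, 610 genes passed. The same scaling moved the median of all genes from 0.04 to 0.22 for long-term against short-term UPM in hippocampus, from 0.01 to -0.18 for short-term UPM against control and from 0 to 0.11 per 10 weeks over 3 to 20 weeks.

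Each exposed library was also set against the control of its tissue, 1 library against 1, so these values carry no test. The number of genes at least 2-fold apart, among those with at least 50 counts in either library, was 1123, 1167, 921 and 855 at 3, 5 and 7 days and 3 weeks in hippocampus, and 391, 142, 397 and 296 at 8, 12, 16 and 20 weeks. In cortex it was 860, 1373, 861 and 1163, then 108, 121, 100 and 121. The 8 early-set libraries thus lay at 855 to 1373 genes (median 1022) and the 8 late libraries at 100 to 397 (median 131.5). At 8 weeks the genes apart in both tissues included Shox2, a thalamic transcription factor gene (log2 ratio 5.43 in hippocampus and 5.82 in cortex), Six3 (4.79 and 1.54) and Prkcd (2.24 and 2.97) on the higher side, and Nmb, the neuromedin B gene, on the lower (-1.89 and -2.85). At 16 weeks the liver genes Alb (3.06 and 3.25) and Mup2 (2.26 and 2.63) were higher in both tissues, and at 20 weeks Mog was lower (-1.06 and -1.66). At 5 days Obp2a, an odorant-binding protein gene of the nasal lining, had 202 and 139 counts where both controls had 0. At 3, 5 and 7 days and 3 weeks Snora81 had log2 ratios of 7.50, 7.27, 7.84 and 8.08 in hippocampus and 7.96, 8.06, 7.69 and 8.85 in cortex. Genes higher in both tissues numbered 87, 107, 44, 94, 14, 5, 12 and 4 from 3 days to 20 weeks, and genes lower in both 214, 263, 193, 222, 2, 0, 2 and 2; each tissue's times shared 1 control.

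**Figure D5:**
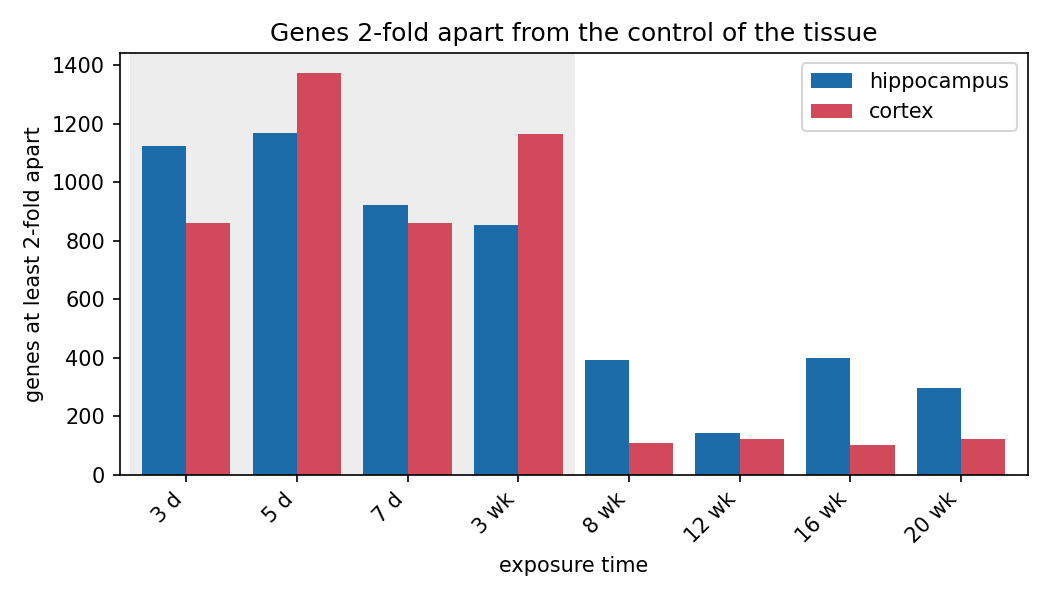
Number of genes at least 2-fold apart from the control of the same tissue, among genes with at least 50 counts in either library, for each exposed library by exposure time; grey shading marks the early set. Early-set bars lie between 855 and 1373 genes and late bars between 100 and 397.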

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

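The tests of batches, of tissue carried over, of a choroid plexus shift common to exposed libraries and of oligodendrocyte RNA below, and all tests within or between library sets, were chosen only after the result was seen.

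In 124 checks, each of 1 measure over the 5 long-term libraries of 1 tissue, 24 had a library far from the others (gap over range above 0.71). Chance gives about 1 in 20 checks, 6.2 here if they were independent, but several measures share genes. Of the 24, 16 were 3-week libraries. In cortex at 3 weeks these were choroid plexus genes (0.731), oxidative phosphorylation genes (0.857), ribosomal protein genes (0.855), long non-coding RNAs (0.789), genes detected at equal total counts with Rn45s included (0.872, 15580 against 16257 to 16356 genes) and the ribosomal protein share (0.761, 2.05% against 1.17% to 1.38%). Single genes in that library were Aif1 (0.773, 20.2 CPM against 9.2 to 11.7), Apoe (0.778, 1930 against 1210 to 1370 CPM), Fos (0.903, 52.3 against 10 to 14.1 CPM) and Ttr (0.928, 1940 against 24.9 to 162 CPM). In hippocampus at 3 weeks they were interferon response genes (0.796), oxidative phosphorylation genes (0.730), ribosomal protein genes (0.967), long non-coding RNAs (0.989), genes detected at equal total counts with Rn45s included (0.812, 15486 against 16696 to 16977 genes) and the ribosomal protein share (0.870, 1.8% against 1.26% to 1.33%).

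Outside the 3-week libraries, thalamus and habenula genes stood apart at 8 weeks in cortex (0.727) and hippocampus (0.711), and hippocampal neuron genes at 12 weeks in cortex (0.803). In hippocampus, neurogenesis and cell cycle genes (0.774) and Gfap (0.736, 174 against 121 to 135 CPM) stood apart at 8 weeks, C4b at 12 weeks (0.712, 17.4 against 11.5 to 13.2 CPM), and circadian clock genes (0.713) and Il1b (0.799, 0.96 against 0.22 to 0.37 CPM) at 16 weeks.

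The long-term against short-term change differed between the tissues for 5 lists by camera. They were mural cells and fibroblasts (adjusted p = 8.7e-06), choroid plexus (0.000109), homeostatic microglia (0.00113), collagens and matrix (0.0244) and ependyma (0.0427). Each had adjusted p = 0.872 with an estimated correlation.

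Between the early set and the control and late set 5486 genes differed. Trends over gene length, genomic span and GC content were not the whole cause, since among the 13338 genes with these values 3772 of 5243 called genes (71.9%) were still called in the same direction after the trends were removed. A response to the first days of UPM that fades step by step was not the whole cause either. On an axis with 0 for the mean of short-term and 1 for that of control and late libraries, 1 library per tissue stood for 3 weeks. It lay at 0.08 in hippocampus (short-term -0.09 to 0.06, SD 0.08) and at -0.09 in cortex (short-term -0.23 to 0.13, SD 0.20). The 3-week libraries were named like the short-term ones, so a fading part beside a batch difference cannot be judged. A difference between sequencing or library batches cannot be told apart from the exposure times, since the naming of the libraries follows the same split, and 4376 genes were called between the sets among long-term libraries alone. A step change between 3 and 8 weeks, from exposure or age, stays open too, though the control has the same place as the late libraries.

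Myelin genes were lower at 20 than at 12 weeks of the control and late set, all 20 in hippocampus (median -1.25, SD 0.36) and all 20 in cortex (-0.46, SD 0.25). In hippocampus the thalamus list moved by 0.01 (SD 0.65) and the striatum list by 0.41 (SD 1.22) over this interval. That argues against a lower share of carried-over thalamus or striatum there, for this interval only. It does not exclude it, since a single library stood for each time. Over 8 to 20 weeks the median log2 ratio to the control went from 1.64 to 0.52 for the thalamus list and from 1.13 to -0.54 for myelin genes in hippocampus, and without 8 weeks the trend had 0 genes in edgeR, so carried-over thalamus stays open for the called trend. In cortex the striatum list fell as well (-1.97, SD 0.73, 16 of 16 genes), so less striatum in the 20-week sample may explain the fall there. With the striatum level as a covariate, 8 of 8 named myelin genes kept a negative slope (median -1.37). That does not decide, since genes were named largely by their fall in this same trend and the fit took both tissues together. The thalamus list (0.01, SD 0.99) does not decide either. Less oligodendrocyte RNA from exposure, from age or from a smaller white matter share cannot be told apart. Weeks of exposure go with age, and no vehicle library is known to be of the same age, since the time of the control is not stated.

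Choroid plexus genes varied between libraries of each tissue. Ttr and the mean of 16 other choroid plexus genes had Pearson r of 0.982 in hippocampus (9 libraries, permutation p = 5.5e-06, adjusted 1.1e-05) and 0.972 in cortex (p = 1.7e-05, adjusted 2.3e-05). Spearman's rho was 1.0 (p = 5.5e-06) and 0.983 (p = 5e-05), and r without the 2 farthest libraries was 0.993 and 0.981, over 4 relations tested. Choroid plexus tissue carried over at dissection may therefore be a source. Below the control lay 1 of 8 exposed libraries in hippocampus and 6 of 8 in cortex, so no shift put all exposed libraries on one side. A smaller common shift cannot be judged, since Ttr spanned 8.33 and 8.86 log2 units within hippocampus and cortex and each tissue had 1 control. No biological explanation was tested.

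Other splits of the same libraries were fitted. Chance was excluded for the tissue difference (2507 genes, as many in 1 of 100 splits, highest other 758). For the library sets (5486 genes, 1 of 100, highest other 3401) the split was taken up after it was seen in the data, so its rank among splits restates the observation. For long-term against short-term UPM in hippocampus (35 genes, 2 of 56, highest other 169) and the trend over 3 to 20 weeks (487 genes, 2 of 60, highest other 840), chance over all splits was excluded. That covers the library sets and not the length of exposure, since some splits that keep the sets apart in the same way gave similar or higher counts. With 3 of the 4 early-set times as short-term the other counts were 4, 30 and 169 genes, and with 3 weeks first, orders of the later weeks reached 481 and 840. Splits with several times the real count point to a structure of the samples, here the library sets.

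With 0 genes in the real split, as for long-term against short-term UPM in cortex and for the difference between the tissues, all 56 of 56 splits are as large by construction and decide nothing (highest other 1376 and 0). With 8 to 20 weeks the 12 orders were too few for a share under 0.05 (40 genes, as many in 1, highest other 8). Comparisons with the control allow only 9 splits, or 5 within the control and late set, too few for a share under 0.05. For short-term UPM (288 genes) 3 other times treated as the control gave more, 359 at 8 weeks, 706 at 16 weeks and 752 at 20 weeks. For long-term UPM (0 genes) the highest other was 2967 at 3 weeks, for UPM of any length (0) 147 at 5 days, and within the control and late set (0) 6 at 8 weeks.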

How the results depend on the processing

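The terms for the library set, the fits within a set, those without Rn45s, Akap5 and Lrrc17, those with a striatum or choroid plexus covariate, and all values for comparisons between or within sets were chosen only after the data were seen. Where a count changes below, the cause was not tested, except that a fold above 1.5 is a stricter test and fits without libraries have fewer samples.

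Of 683 results for named genes, 176 passed, and 169 of these kept their direction under every alternative run. Over all alternatives 47 of the 176 stayed past the threshold, 23 of 51 for tissue and 24 of 44 for the library sets, and 0 of 13 for long-term against short-term UPM in hippocampus, 0 of 22 for short-term UPM, 0 of 32 for the trend and 0 of 14 for that within the late set. Among 18975 alternative values 17208 kept side and direction, 1276 lost the threshold, 442 gained it, 36 moved and 13 reversed. With the set as a term the short-term change against control reversed for Col6a1 (0.12) and Col4a2 (0.01). In comparisons with short-term libraries that term rests on 3 weeks against the later weeks, and does not tell the set from time. The trend over weeks reversed for Ccdc36 (0.11), Timm22 (0.10) and Bc1 (0.18) without 3 weeks, with the set as a term and within the control and late set alike, and for Snora81 (0.42) with the set as a term. The set difference of Mt1 reversed among long-term libraries only (0.03).

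The tissue difference (2507 genes, 1130 higher in hippocampus and 1377 lower) was 1446 higher and 980 lower with total counts only, 349 with a fold above 1.5, 656 within the early set and 1912 to 2458 without 1 library. The set difference (5486) was 610 with a fold above 1.5, 2980 in hippocampus only and 5102 to 5523 without 1 library.

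Long-term against short-term UPM in hippocampus (35 genes) was 1116 with DESeq2, 0 with limma-voom, 1 with RLE size factors, 558 with total counts only, 266 with no filter, 85 with a mean of 50 counts in every group and 0 with a fold above 1.5. It was 66 without region, blood and top genes, 1 without Rn45s, Akap5 and Lrrc17, 0 with the set as a term, 0 within the early set and 2433 with 3 weeks counted as short-term. Leaving out 1 library gave 0 to 2195: 0 without 3, 5 or 7 days or 8 weeks, 2195 without 3 weeks (1117 higher and 1078 lower, against 29 and 6), 2 without 12 weeks and 1 without 16 or 20 weeks. In cortex (0 genes with edgeR, 3081 at an unadjusted p under 0.05) it was 667 with DESeq2, 9 with limma-voom, 60 with no filter, 3352 with 3 weeks counted as short-term and 0 to 3041 without 1 library, 3041 without 3 weeks. The difference between the tissues (0, 1252 at an unadjusted p under 0.05) was 25 with DESeq2 and 0 with limma-voom and without any 1 library.

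UPM against control (0 genes with edgeR, DESeq2 and limma-voom, 272 at an unadjusted p under 0.05) stayed at 0, but 5 days, 3 weeks and 8 weeks treated as if they were the control gave 147, 1 and 1. Within the control and late set (0 with each tool, 676 at an unadjusted p under 0.05) it was 0 to 4 without 1 library, 1 without the hippocampal and 4 without the cortical control. Long-term UPM against control was 0 in every alternative run (185 at an unadjusted p under 0.05), but 2967 with 3 weeks, 395 with 5 days, 6 with 8 weeks, 4 with 3 days and 1 with 7 days treated as the control.

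Short-term UPM against control (288 genes) was 991 with DESeq2, 803 with total counts only (55 higher and 748 lower, against 47 and 241), and 0 with a fold above 1.5, with time as a random block, with both tissues summed and with the set as a term. Without a time in both tissues it was 0 (5 days), 167 (7 days), 2011 (3 weeks), 19 (8 weeks), 18 (12 weeks), 72 (16 weeks) and 171 (20 weeks). Without 1 library it was 0 to 1169: 0 without either control or cortex 5 days, 74, 156, 825 and 186 without hippocampus 5 days, 7 days, 3 weeks and 12 weeks, and 1169, 167 and 179 without cortex 3, 12 and 16 weeks. With another time treated as the control it was 359 (8 weeks), 706 (16 weeks), 752 (20 weeks), 30 (5 days), 2 (3 weeks), 1 (3 days) and 0 (7 days and 12 weeks).

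The trend over 3 to 20 weeks (487 genes) was 1609 with DESeq2, 183 with total counts only (120 rising and 63 falling, against 142 and 345), 893 with a mean of 50 counts, 2 with a fold above 1.5, 20 with time as a random block, 0 with both tissues summed, 31 with the set as a term, 40 within the control and late set and 2912 on log2 weeks. Without a time it was 40 (3 weeks), 2697 (8 weeks), 0 (12 weeks), 0 (16 weeks) and 6 (20 weeks). Without 1 library it was 0 to 1720: 0, 1408, 19, 42 and 87 without hippocampus 3, 8, 12, 16 and 20 weeks, and 0, 1720, 17, 21 and 8 without cortex. Over 8 to 20 weeks (40 genes) it was 101 with DESeq2, 25 with total counts only, 62 with no filter, 0 with a fold above 1.5, 10 with both tissues summed, 22 on log2 weeks and 18 with a striatum covariate. Without a time it was 0 (8 weeks), 14 (12 weeks), 89 (16 weeks) and 2 (20 weeks), and without 1 library 0 to 71: 0, 71 and 13 without hippocampus 8, 16 and 20 weeks, and 0, 17 and 14 without cortex 8, 12 and 20 weeks.

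For each exposed library against the control of its tissue, the median number of genes 2-fold apart (626) was 1067 with a minimum of 20 counts and 214 with 200. Of 304 list and comparison pairs camera called 79, against 3 with an estimated correlation and 20 with fry. Not run for lack of the groups were fits within the early set for the comparisons with control and the trend, within the control and late set for those with short-term libraries, and without the control in both tissues. A floor of 3 counts, 0.335 to 0.552 CPM, limits ratios of genes near 0, and simulated 1.5-fold changes were recovered for 1.49% of genes for short-term UPM to 53.7% for the library sets.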

Other observations

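Everything in this part, the test included, was chosen only after the values were seen.

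The control was the lowest of 9 libraries in both tissues for activated microglia genes. UPM exposure may have raised them. The test counted how many of the 38 lists had the control at one end of the 9 libraries in both tissues, which was 2, with 0.94 expected by chance, and 3.04 expected against 4 found within the control and late set. Blood leukocyte and red blood cell genes also lay above the control by their medians (2.03 and 0.75), but not in every library. The leukocyte list (4 genes) was highest at 5 days, at 1.57 in hippocampus and 2.53 in cortex. In cortex it lay below the control (-0.46) at 7 days (-0.83), 12 weeks (-0.53) and 20 weeks (-0.94). For red blood cell genes the control ranked 2 of 9 from below in both tissues. Whether blood cells were a source was not tested. The count of lists does not decide, since each tissue had 1 control, taken at an unstated time, and the same mice may have given both.

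The 5-day libraries of both tissues held transcripts of the nasal lining and glands. Obp2a had 202 counts in hippocampus and 139 in cortex, at most 1 in the 16 other libraries, Obp2b 57 and 49, at most 2, and Obp1a 50 and 51, at most 6. Lcn11 had 32 and 35 counts, at most 1, and Scgb3a1 27 and 18, at most 4. Of the acute-phase and neutrophil genes, the same libraries had Lcn2 at 57 and 77 counts, at most 5 elsewhere, Lrg1 at 59 and 123, at most 37, and S100a8 at 33 and 195, at most 21. S100a9 had 99 and 165 counts there but also 80 in hippocampus at 20 weeks, 61 in cortex at 3 weeks and 54 in cortex at 3 days. The red blood cell genes Hba-a1 and Hbb-bs were also highest at 5 days within each tissue. In hippocampus and cortex Hba-a1 stood at 1070 and 1510 CPM of total counts against 413 and 445 in the controls. Hbb-bs stood at 416 and 825 against 208 and 191.

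Liver transcripts were highest at 16 weeks in hippocampus, with Alb at 340 CPM of total counts, Mup2 at 118, Apoa1 at 92.8, Serpina1c at 70.8 and Serpina3k at 69.6, against 39.6, 23.9, 18.3, 10.7 and 26.7 CPM in the hippocampal control. In cortex Alb stood at 34.4 CPM at 8 weeks and 27.1 at 16 weeks against 2.67 in the control, and Apoa1 at 12.0 and 7.05 against 2.54. Shox2 had 331 and 156 counts in the 8-week hippocampus and cortex, and at most 39 in the 16 other libraries.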
